A study of Mus musculus with 20 samples.

How the data were processed

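Messenger RNA was sequenced from intestinal epithelial scrapings and liver of i-KO and WT mice, with 5 libraries per tissue and genotype, as the labels give them. Each library has a number in its title. Some numbers occur in both tissues, and no label says that a number stands for a single animal. Libraries were stranded and poly-A selected, and the intestine libraries were sequenced in 2 runs that were merged, per the labels' protocols. FastQC, STAR and the genome build mm9 are listed, with no versions, per the submitters' processing notes. The counting program, the gene annotation and the formula of the coverage values are not given in the sources used here.

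The authors deposited 1 table per library with a gene symbol and a gene coverage (signal) value to 1 decimal, without a header. The deposited coverage values are not whole numbers and their totals differ between libraries. They were therefore treated as neither whole-number counts nor a per-million unit. Fractional counts are not excluded. The planned test was a count test (edgeR), which was not used because the values are not counts; a linear model on log values replaced it. DESeq2 and voom were not run for the same reason. All 24421 symbols occur in the same order in the 20 tables. Of these, 23204 match a current symbol and 1109 an older one in the RefSeq annotation of a later mouse build (GRCm38), which was used for names only. Gene positions are not given, since no annotation of the build of the files was used here.

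From the deposited coverage the following was computed. Within each tissue, values were divided by the library total and an unweighted trimmed mean of M-values (TMM; trimming 0.3 of ratios and 0.05 of levels) and expressed per 1000000. Genes with at least 1 per 1000000 in at least 5 libraries of the tissue were tested. The model was fitted to log2(value + 1), with a pseudocount of 1, in limma 3.58.1 under R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, two-sided. Each tissue was fitted alone, with i-KO minus WT as the contrast. The difference between tissues was tested as an interaction over the 4 groups of 20 libraries, on genes tested in both tissues, with scaling within tissue. Gene lists were tested by camera with a preset inter-gene correlation of 0.01, adjusted over the lists of the tissue, and beside it with an estimated correlation and by fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

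Groups, the gene lists of the 3 comparisons and the rule for named genes were set before the data were examined. The linear model was chosen after the unit of the values was seen, and the lists of the last section were written after leading genes were seen. Named genes are, per tissue, 5 fixed genes, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5, non-overlapping groups and an established symbol, and up to 4 members per list with the smallest p. For the interaction they are the 10 genes with the smallest p under the same exclusions. Members named beyond this rule (Npc1l1 and Cck, the single members of their lists past the threshold in the direction opposite to the list) were chosen after their values were seen. The lists covered sterol, isoprenoid, fatty acid and LXR pathways, proliferation, stress, clock, stem cell and lineage markers, segment markers, and markers of other cell types in each tissue. Exocrine pancreas had 1 tested member, so it has no list test.

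The steps were tested on simulated coverage with the real means, spreads and totals and a small set of changed genes. Simulated genes varied independently of each other. The shares and false calls below therefore do not carry over to data with correlated genes or many changed genes. In simulated intestine with 11959 genes, 40.3% of 1.5-fold, 60.0% of 2-fold and 87.5% of 4-fold changes were called, with 8 false calls. In simulated liver with 11171 genes the shares were 26.2%, 70.8% and 96.8%, with 5 false calls. For the interaction with 10015 genes they were 14.1%, 54.5% and 95.3%, with 9 false calls.

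No 2 libraries were identical. Spearman correlations within a genotype were 0.921 to 0.988 in intestine and 0.929 to 0.977 in liver. The smallest step of 0.1 coverage units equals 0.568 per 1000000 in intestine i-KO 1, the shallowest library, and 0.0829 to 0.152 in the other intestine libraries, so low genes are measured least well in i-KO 1. The sex of the mice is not given in the labels. Xist was 51.2 and the Y-linked genes were at 0 in intestine WT 9, and the reverse held in the other 19 libraries (Xist at most 0.124). A sex covariate was planned for the case that both sexes occur in both genotypes, and was not run because they do not. Alternatives tried were other scalings, filters and pseudocounts, precision and library weights, a joint fit of both tissues, and leaving out libraries.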

Results

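Messenger RNA was measured by stranded, poly-A selected RNA sequencing in mice aged 5 weeks on the C57Bl6/J background. Hmgcr encodes 3-hydroxy-3-methylglutaryl coenzyme A reductase, the rate-limiting enzyme of the mevalonate pathway that makes cholesterol and isoprenoids. In i-KO mice both Hmgcr alleles were floxed and a Cre recombinase was driven by the villin promoter, which is active in intestinal epithelium. The WT mice carried the same Cre with unmodified Hmgcr. Epithelial scrapings of the intestine were sequenced from 5 i-KO and 5 WT mice, and liver from 5 i-KO and 5 WT mice. The intestinal segment of each scraping is not given in the labels. Each library is a table of 24421 gene symbols with a coverage value per gene. Summed coverage ranged from 672173 to 1205585 in 9 intestine libraries and was 179136 in intestine i-KO 1. In liver it ranged from 458042 to 1930531. The depth in reads is unknown from these tables, so no counting interval is given. All values below are coverage per 1000000 after scaling, as mean ± SD with n = 5 per group, and fold changes are on the log2(value + 1) scale, which understates changes of low genes.

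Hmgcr itself was read first. In intestine it was 41.7 ± 12.4 in i-KO and 51.8 ± 5.34 in WT, a log2 fold change of -0.35 ± 0.18 (SE) that did not pass the test (limma adjusted p = 0.146). The Hmgcr values of the single i-KO libraries were 27.8, 36.6, 45.1, 38.0 and 61.0 in replicates 1, 2, 3, 5 and 6. In WT replicates 7, 8, 9, 10 and 12 Hmgcr was 55.7, 47.4, 49.1, 59.1 and 47.5. Without i-KO 6 the Hmgcr difference passed the test, at a log2 fold change of -0.49 (limma adjusted p = 0.0221). The deleted part of the gene is not stated in the labels, so the coverage of the whole Hmgcr gene does not check the deletion. In liver, where the villin promoter is not active in hepatocytes, Hmgcr was 22.2 ± 7.16 in i-KO and 19.0 ± 6.26 in WT (log2 fold change 0.21 ± 0.24, limma adjusted p = 0.839).

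**Figure D1:**
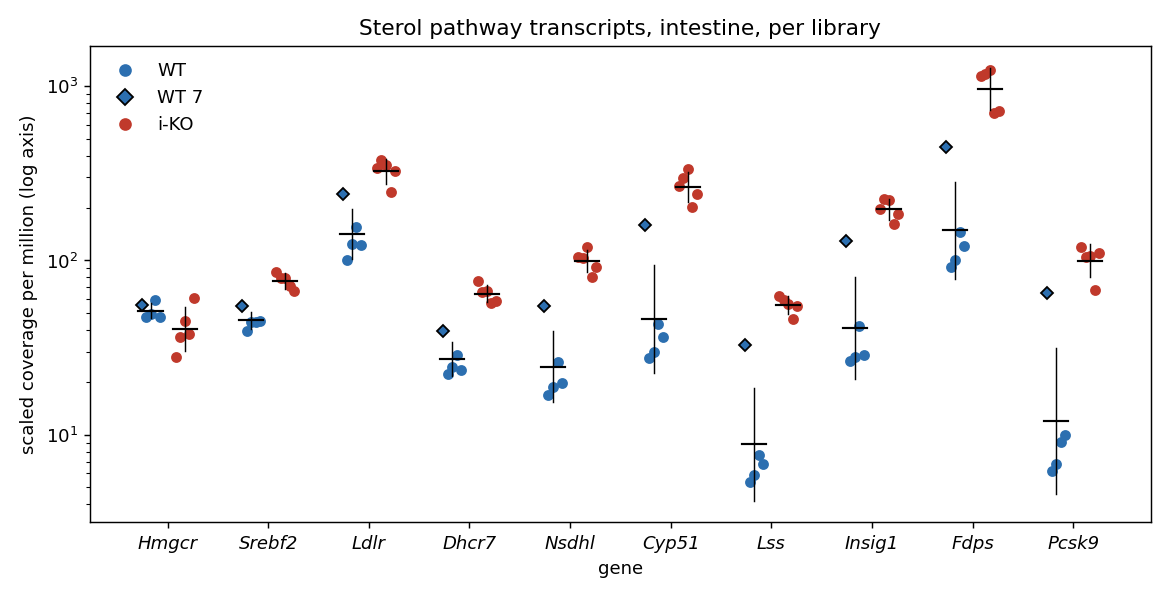
Scaled coverage per 1000000 (log axis) of Hmgcr and 9 sterol pathway genes in each intestine library; circles are libraries, the diamond is WT 7, horizontal bars are geometric means and vertical bars are 1 SD of the log2 values (n = 5). Fdps averaged 997 in i-KO and 182 in WT, whereas the Hmgcr values of the groups overlap; WT 7 lies above the other 4 WT libraries for each of the 9 sterol genes.

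The first comparison asked which transcripts of the intestinal epithelium differ when the epithelium carries the Hmgcr deletion. Of 19 cholesterol synthesis genes 17 were higher in i-KO, and so were 24 of 25 cell cycle genes. Of the mature cell markers 12 of 22 for enterocytes, 9 of 14 for Paneth, 6 of 7 for tuft and 8 of 14 for enteroendocrine cells were lower, and 1 enteroendocrine marker was higher. With an estimated correlation none of these lists was called (adjusted p from 0.352 to 0.450). Of 11721 genes tested, 4124 changed (limma, adjusted p under 0.05), with 2177 higher and 1947 lower in i-KO. This balance depended on the scaling, with 2032 higher and 2169 lower by upper quartiles and 2391 and 1544 by library totals. Of the 4124, 620 were higher and 432 were lower by at least 2-fold. The groups did not overlap for 2033 genes, 17.3% of those tested, against 0.794% by chance.

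Cholesterol synthesis enzymes other than Hmgcr rose together in i-KO intestine. Of 19 tested members 17 rose, none fell, and the same 17 passed when adjusted over the list alone; the median log2 fold change was 1.97. The list was called by camera (adjusted p = 3.85e-11) but not with an estimated inter-gene correlation, where the adjusted p = 0.352. Fdps, the farnesyl diphosphate synthase, rose from 182 ± 150 to 997 ± 261, a log2 fold change of 2.69 ± 0.38 (limma adjusted p = 0.00172). Pmvk, Lss and Cyp51 rose by 2.41, 2.50 and 2.49 on the log2 scale, and Dhcr7, which makes the last step, by 1.22. Nsdhl rose from 27.3 ± 15.7 to 100.0 ± 14.4. The list's mean log2 level in WT 7 was 6.66, between 5.01 to 5.44 in the other 4 WT libraries and 7.03 to 7.55 in i-KO.

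Genes of sterol uptake and of the SREBP2 feedback loop moved with them. Of 8 tested, 6 rose and 1 fell, over all genes and when adjusted over the list alone (camera adjusted p = 0.00721; adjusted p = 0.370 with an estimated correlation). Pcsk9, whose product lowers LDL receptor levels, rose from 19.4 ± 25.5 to 102 ± 19.7 (log2 fold change 2.93 ± 0.51). Its WT SD exceeded its WT mean, and WT 7 was the highest of the WT libraries. Insig1 rose by 2.23, Ldlr by 1.19 ± 0.21 and Srebf2 by 0.74 ± 0.11 on the log2 scale. The member that fell was Npc1l1, the intestinal cholesterol importer, at a log2 fold change of -0.84. In fatty acid synthesis 9 of 12 tested genes rose and none fell, and 9 rose when adjusted over the list alone (median 1.21, camera adjusted p = 3.92e-05; adjusted p = 0.352 with an estimated correlation). Fasn rose from 7.12 ± 4.37 to 24.4 ± 2.59 and Acss2 from 16.3 ± 7.07 to 51.5 ± 9.91. Scd2, a stearoyl-CoA desaturase outside the list, had the largest rise among the named genes, from 25.5 ± 36.6 to 160 ± 14.4 (log2 fold change 3.35 ± 0.54, limma adjusted p = 0.00208). WT 7 carried the WT mean of Scd2, at 90.9 against 8.37 to 9.85 in the other 4 WT libraries, and without it the log2 fold change was 3.99. WT 7 lay between the groups for both lists, with mean log2 levels of 6.52 and 3.83.

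Targets of the oxysterol receptor LXR fell. Of 9 tested, 5 fell and none rose, over all genes and when adjusted over the list alone (camera adjusted p = 0.00608; adjusted p = 0.443 with an estimated correlation). Abcg5 and Abcg8, which together export sterols to the gut lumen, fell from 390 ± 102 to 166 ± 27.5 and from 520 ± 132 to 233 ± 47.0, and Abca1 fell from 12.8 ± 5.97 to 3.16 ± 2.48. In the PPARA and fatty acid oxidation list 3 of 10 fell and none rose, with the same count when adjusted over the list alone and 5 lower without WT 7 (camera adjusted p = 0.0299; adjusted p = 0.450 with an estimated correlation). These were Vnn1, Acaa1b and Pdk4, and Pdk4 went from 30.4 ± 17.2 to 4.75 ± 5.36. Among enzymes of the nonsterol isoprenoid branch 5 of 14 rose and 1 fell, likewise when adjusted over the list alone, with 2 higher without i-KO 1 or without WT 9, and the list was not called (camera adjusted p = 0.185). Pdss1 and Pdss2, which make the ubiquinone side chain, rose by 0.78 and 0.82 on the log2 scale. Fntb, a farnesyltransferase subunit, fell by 0.55.

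Proliferation genes rose in i-KO intestine, 24 of 25 over all genes and when adjusted over the list alone, with a median log2 fold change of 1.41 (camera adjusted p = 3.19e-12; adjusted p = 0.352 with an estimated correlation). Ccna2 rose from 14.3 ± 7.11 to 44.1 ± 8.80 and Top2a from 12.3 ± 6.63 to 35.3 ± 4.25. The replication licensing genes Mcm3 and Mcm4 rose by 1.65 and 1.29 on the log2 scale. WT 7 had a mean log2 level of 4.06 for this list, against 2.72 to 3.30 in the other 4 WT libraries and 4.295 to 4.68 in i-KO. Of 18 tested stem cell markers 6 rose and none fell, and 6 rose when adjusted over the list alone (median 0.39, camera adjusted p = 0.0221; adjusted p = 0.522 with an estimated correlation). Cd44 rose from 16.6 ± 13.2 to 44.9 ± 12.6, and Ephb2, Igfbp4 and Cdca7 rose by 1.19, 1.02 and 0.84 on the log2 scale. Lgr5, the marker of crypt base columnar stem cells, did not pass the test at 0.691 ± 0.432 in i-KO and 1.12 ± 0.108 in WT (limma adjusted p = 0.201), close to the minimum level for testing. Olfm4 was 150 ± 72.9 in i-KO and 102 ± 41.5 in WT (limma adjusted p = 0.2998).

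Markers of the differentiated lineages were mostly lower. Among enterocyte markers 12 of 22 fell and none rose, and 13 fell when adjusted over the list alone. The number that fell was 9 without WT 9 and 15 without WT 7. The list's median was -0.66 (camera adjusted p = 0.000100, and adjusted p = 0.450 with an estimated correlation). The lactase gene Lct fell from 640 ± 193 to 120 ± 60.9, and Ace fell from 1842 ± 606 to 461 ± 127. Apob, the chylomicron apolipoprotein, fell by 0.87 on the log2 scale. Paneth cell markers fell in 9 of 14 cases, and in 11 when adjusted over the list alone (median -1.63, camera adjusted p = 0.000164; adjusted p = 0.450 with an estimated correlation). Defa21 and Defa22 fell by 2.39 and 2.43 on the log2 scale; alpha-defensin genes are near-identical copies, so their separate values are uncertain. Tuft cell markers fell in 6 of 7 cases, and in 7 when adjusted over the list alone (median -1.28, camera adjusted p = 0.000370; adjusted p = 0.352 with an estimated correlation). Dclk1 went from 5.51 ± 1.53 to 1.02 ± 0.826 and Rgs13 from 7.79 ± 2.63 to 1.16 ± 0.888. Mean log2 levels in WT 7 were 10.2 for enterocyte and 2.25 for tuft markers, the lowest of the 5 WT libraries in both lists.

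Enteroendocrine markers fell in 8 of 14 cases and rose in 1, also when adjusted over the list alone (camera adjusted p = 0.00337; adjusted p = 0.352 with an estimated correlation). Sst fell from 61.2 ± 19.1 to 16.5 ± 4.87, Nts by 1.24 and Gip by 0.97 on the log2 scale, and Cck was the member that rose (log2 fold change 0.59). Of 11 goblet cell markers 6 fell and 1 rose, over all genes and when adjusted over the list alone, with 3 lower and 0 higher without WT 9, and the list was not called (camera adjusted p = 0.0841). Muc2, the main secreted mucin, went from 380 ± 77.1 to 225 ± 34.8, whereas Agr2 rose by 0.74 on the log2 scale. WT 7 was at 5.00 for enteroendocrine markers, the lowest of the WT libraries.

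Genes of the ER stress and ATF4 list rose in 9 of 15 cases, and when adjusted over the list alone 9 rose and 1 fell (camera adjusted p = 0.00608; adjusted p = 0.450 with an estimated correlation). Asns, the asparagine synthetase, rose from 10.5 ± 4.93 to 44.9 ± 12.3 and the chaperone-like Pdia4 from 36.1 ± 8.69 to 78.2 ± 18.6. In the antimicrobial list 2 of 8 rose and 1 fell, likewise when adjusted over the list alone, with 1 higher without WT 9 and 3 without WT 7 (camera adjusted p = 0.390). Duoxa2 and Duox2 rose by 1.69 and 1.29 on the log2 scale and Reg3a fell from 387 ± 46.5 to 138 ± 50.6. Circadian clock genes fell in 5 of 13 cases, also when adjusted over the list alone (3 without WT 9, 7 without WT 7), and the list was not called (camera adjusted p = 0.0841). Nr1d1 went from 87.7 ± 22.5 to 33.3 ± 9.81 and Dbp from 23.0 ± 12.4 to 5.50 ± 6.21. In the YAP and regenerative list 1 of 10 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.822). Areg rose by 1.88, and Amotl2 and Lats2 fell by 1.76 and 0.93 on the log2 scale. The list's median was 0.02, its mean 0.02 and its camera direction down, and the median changed sign between scalings.

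Markers of segments and of other cell types were measured beside these. Of 4 proximal markers 2 fell, Bco1 and Lct, with log2 fold changes of -3.43 and -2.51, with the same count when adjusted over the list alone (camera adjusted p = 0.0632); Gata4 was 40.1 ± 8.58 in i-KO and 40.9 ± 3.48 in WT. Of 6 ileal markers 2 rose and 1 fell (2 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.865). Fabp6, the ileal bile acid binding protein, rose from 912 ± 1272 to 4821 ± 3255, Slc10a2 rose by 1.60 and Cubn fell by 3.09 on the log2 scale. None of 12 smooth muscle and stroma markers changed, over all genes or adjusted over the list alone (camera adjusted p = 0.514). Their mean log2 level was 4.01 in i-KO 5 against 1.05 to 2.14 in the other i-KO libraries and 1.86 to 2.79 in WT, which widened the i-KO spread (SD 1.14 against 0.364), and 457 genes were at least 3 times higher in i-KO 5 than in the 8 libraries other than WT 7. Among 15 leukocyte markers Cd8a fell, by 1.01 on the log2 scale, and none passed when adjusted over the list alone (camera adjusted p = 0.822). For leukocytes the median was -0.17 and the mean 0.04, and the mean log2 level was 5.44 in i-KO 5 against 1.76 to 3.32 in the other 4 i-KO libraries. None of 4 blood cell markers changed by either adjustment (camera adjusted p = 0.865). Clps was the single pancreatic gene tested, also alone in its list, and fell by 1.57 on the log2 scale.

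The other named genes with the largest changes came from several functions. Higher in i-KO were Psat1 of serine synthesis (6.56 ± 6.12 to 40.5 ± 11.8), Mboat1, Ckb, Chac1 and H2-Q10, with log2 fold changes of 2.71, 2.87, 2.62, 2.57 and 2.48 in that order. The largest fall was that of Cd36, a fatty acid transporter, from 173 ± 53.7 to 11.4 ± 8.05 (log2 fold change -3.94 ± 0.39, limma adjusted p = 0.000602). The deiodinase Dio1 fell from 161 ± 50.1 to 14.5 ± 3.61 (log2 fold change -3.36 ± 0.24). Lect2 was listed at 0 in 4 of the 5 i-KO libraries and averaged 12.3 ± 4.08 in WT. Cyp2c66, Cyp3a25, Bmp1, Iyd and Olfr165 fell by 3.67, 3.09, 3.51, 3.08 and 3.06 on the log2 scale. In all, 12 of the 22 lists with at least 2 tested genes were called with the preset correlation and 0 with the estimated one.

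**Figure D2:**
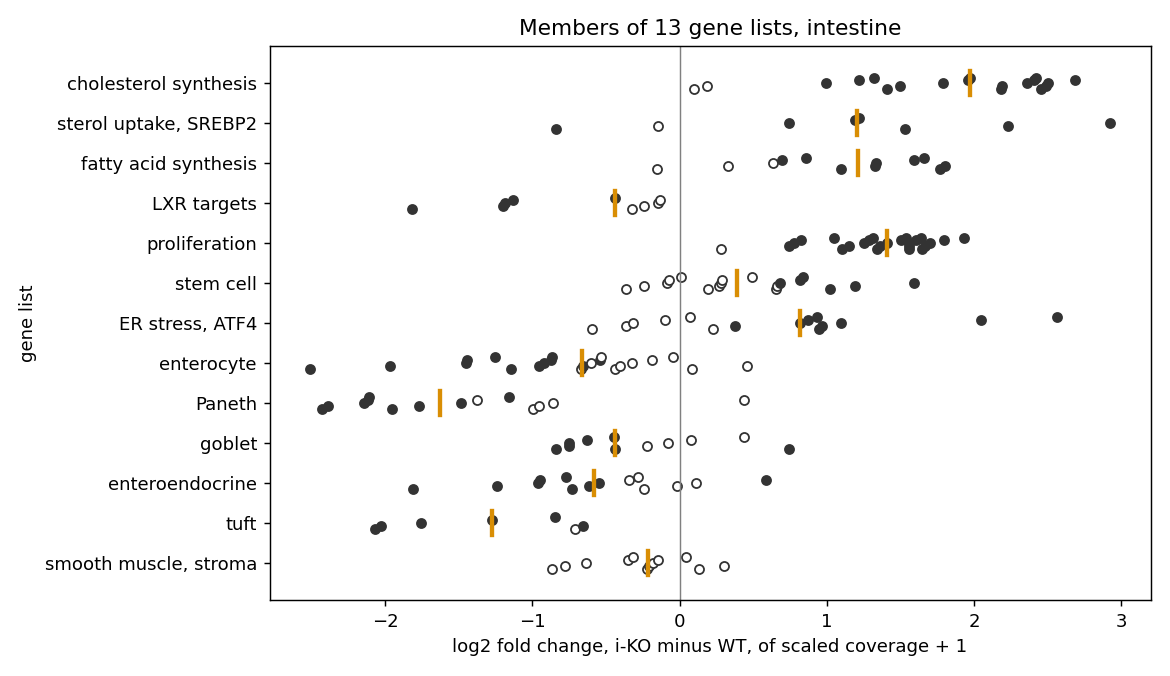
Log2 fold change (i-KO minus WT, of scaled coverage + 1) of each tested member of 13 gene lists in intestine; filled points passed the limma test over all genes, open points did not, and the orange bar is the list's median. The medians are 1.97 for cholesterol synthesis and 1.41 for proliferation, and -1.63 for Paneth markers.

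The second comparison asked which liver transcripts differ when the intestine carries the deletion. No liver gene passed the test. Of 11205 genes tested 0 had a limma adjusted p under 0.05, and the smallest adjusted p = 0.290. At an unadjusted p under 0.05 there were 851 genes, where 560 are expected by chance, and with precision weights (vooma) the counts were 0 and 850. The unadjusted count ran from 461 (without i-KO 1) to 1534 (without i-KO 6) when single libraries were left out, so its excess over chance depended on single libraries. The groups did not overlap for 108 genes, 0.964% of those tested, against 0.794% by chance. Srebf2 was 11.3 ± 2.70 in i-KO and 12.4 ± 3.91 in WT, Ldlr 77.6 ± 8.60 and 82.9 ± 22.3, Pcsk9 12.1 ± 3.22 and 10.1 ± 5.84, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 28.8 ± 16.7 and 39.2 ± 28.0. Simulated liver data, with 11171 genes that varied independently, gave calls for 70.8% of genes changed 2-fold and 26.2% of those changed 1.5-fold.

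In liver 4 of 20 lists were called by camera although no single member passed, over all genes or adjusted over the list alone. Proliferation genes had a median log2 fold change of 0.34 with 20 of 22 members above 0 (camera adjusted p = 1.48e-05), and Ccnb2 was 5.67 ± 3.67 in i-KO and 2.61 ± 1.49 in WT. Fatty acid synthesis had a median of 0.27 with 12 of 13 members above 0 (camera adjusted p = 0.00720), and Thrsp was 618 ± 409 against 222 ± 113. Male-biased transcripts had a median of -1.45 with all 8 members below 0 (camera adjusted p = 0.00170). Mup20, a major urinary protein, was 2393 ± 2327 in i-KO and 8685 ± 5973 in WT. Acute phase genes had a median of -0.21 with 13 of 15 below 0 (camera adjusted p = 0.0216), and Fgg was 2963 ± 862 against 4081 ± 645. For each of these 4 lists the adjusted p = 0.780 with an estimated correlation. Without i-KO 2 the number of lists called was 7, and without WT 11 it was 2.

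The other liver lists were not called. Cholesterol synthesis had a median log2 fold change of 0.08 over 19 genes (camera adjusted p = 0.244) and sterol uptake -0.07 over 7 genes, with a mean of 0.08 (adjusted p = 0.716). Bile acid synthesis and transport had a median of -0.12 over 17 genes (adjusted p = 0.244), with Cyp7b1 at 31.3 ± 24.3 in i-KO and 101 ± 77.5 in WT. Medians were -0.05 for nonsterol isoprenoid enzymes, 0.05 for LXR targets, 0.11 for PPARA targets and -0.28 for drug-metabolizing enzymes (camera adjusted p from 0.371 to 0.545). Female-biased transcripts had a median of 1.68 over 4 genes (adjusted p = 0.0544) and circadian genes of 0.51 over 12 genes (adjusted p = 0.142). The ER stress, Kupffer cell, cholangiocyte and blood lists had medians of -0.06, -0.09, -0.07 and -0.11, and leukocyte markers, whose median changed sign between scalings, of 0.00 (camera adjusted p from 0.660 to 0.810). Stellate cell and endothelial markers had medians of 0.28 and 0.13 (both adjusted p = 0.244). When adjusted over the list alone, no member of any of these lists passed except 2 ER stress genes, Atf3 at 0.940 ± 0.299 against 2.28 ± 1.02 and Dnajb9 at 8.76 ± 2.68 against 15.6 ± 4.49.

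**Figure D3:**
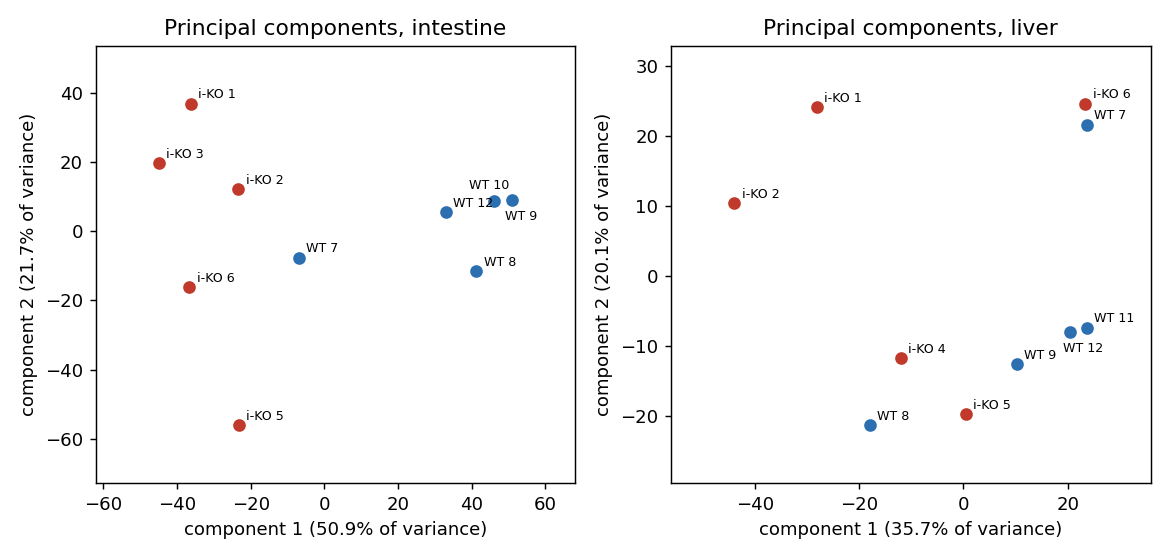
First 2 principal components of log2(scaled coverage + 1) in each tissue, with their share of the variance on the axes; each point is a library, red for i-KO and blue for WT. In intestine the first component holds 50.9% of the variance and WT 7 lies between the i-KO and the other WT libraries; in liver i-KO 6 and WT 7 lie side by side.

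The third comparison asked for which genes the genotype effect differs between intestine and liver. Genes that fell in intestine with little difference in liver led this list. Dio1 had a log2 fold change of -3.36 in intestine and -0.01 in liver, a difference of -3.35 ± 0.31 (limma adjusted p = 1.04e-05). Cd36, Lect2 and Iyd had differences of -4.24, -3.86 and -3.05 on the log2 scale, and Pbld1, Zfp467, Krba1, Pipox and Nrn1 differences of -2.38, -2.32, -2.34, -2.33 and -1.71. Cse1l, a nuclear export factor, was the one named gene with a higher effect in intestine (1.31 ± 0.17). In all, the effect differed for 1829 of 9985 genes tested, with 1067 higher and 762 lower in intestine; with the 16 libraries whose number occurs in both tissues the count was 156.

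By list, 17 of 19 cholesterol synthesis genes had a higher effect in intestine (median difference 1.76, camera adjusted p = 1.43e-12; adjusted p = 0.235 with an estimated correlation). The counts higher were 5 of 7 for sterol uptake, 4 of 12 for fatty acid synthesis, 11 of 22 for proliferation and 4 of 15 for ER stress, where 1 was lower. LXR targets had 2 of 9 lower, PPARA targets 2 of 10 and circadian genes 5 of 12, with a median difference of -1.13. These lists were called by camera (adjusted p from 3.34e-07 to 0.0194) and not with an estimated correlation (adjusted p from 0.235 to 0.290). Nonsterol isoprenoid enzymes, with 2 higher and 1 lower, were not called (camera adjusted p = 0.152), nor were leukocyte and blood markers, with 0 called genes each (adjusted p = 0.986 and 0.965). Of the genes called in intestine 3462 were tested in liver, where 51.5% had the same sign, and their median absolute log2 fold change was 0.67 in intestine and 0.14 in liver. Scaling over all 20 libraries shifted the median difference of all genes from 0.03 to -0.08 and the share of calls that were higher from 58.3% to 39.5%. Without intestine WT 9 the count was 1158.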

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

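The tests of segment, crypt content, liver RNA and sex were chosen after the results were seen. Libraries far from the others of their group were sought among depth, sex genes, fixed genes and list levels, 122 group comparisons in all. A library stood apart in 19, where chance gives about 6.1 (1 in 20).

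Intestine WT 7 lay between the genotypes. Its cholesterol synthesis level of 6.66, PPARA level of 5.64 and tuft level of 2.25 stood apart from the other WT libraries (5.01 to 5.44, 6.29 to 6.42 and 2.86 to 3.06, mean log2). Over 1162 genes called at over 2-fold without it, its median position was 0.63 of the way from WT to i-KO, against -0.08 to 0.16 for the other WT libraries and 0.80 to 1.16 for i-KO. An unmixed i-KO library with a wrong label is argued against. Of 15 genes with strongly separated groups, 93.3% were over 2 times the highest i-KO library in WT 7. For an i-KO library held out in the same way the share was at most 32.4%. An i-KO library that also holds WT RNA would pass this check too, so that explanation stays open. RNA from liver is present (Alb 24.0, at most 0.987 in the other intestine libraries) but abundant liver transcripts reached a median of 0.0415% of their liver level, far too little to move other genes. RNA of i-KO 6 mixed into WT 7 is another candidate explanation that stays open. In WT 7 the 14 genes at least 3 times higher in i-KO 6 than in the 8 other libraries lay at a median share of 0.415. Genes private to i-KO 1, 3 or 5 lay at a median of no more than 0.0871, the value of 7 genes of i-KO 3. In i-KO 2 there were 0 private genes, so it could not be compared. The median share of 0.415 was lower than the median position of 0.63, and this gap was not explained. Liver i-KO 6 and WT 7 were also the most alike pair in liver (Spearman 0.982), which mixing of intestine RNA alone would not give. A biological difference of the WT 7 mouse was not tested.

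Higher proliferation genes with lower mature cell markers in i-KO intestine could come from scrapings with more crypt tissue. The crypt-base Paneth markers had a median log2 fold change of -1.63. More crypt tissue alone would raise these markers, but they are among the lower markers that make the pattern. The check therefore cannot tell whether crypt content differed together with a fall in Paneth markers. A more distal segment cannot be told apart from the genotype effect, because ileal markers went both ways (median log2 fold change 0.0677; Fabp6 up, Cubn down) and the labels give no segment per sample. The genotype itself remains an open, untested biological explanation.

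The male-biased list had a median below 0 in i-KO liver, with 0 of 8 members past the test. The list was lowest among i-KO livers in i-KO 1 and i-KO 2 (mean log2 levels 5.11 and 3.31 against 6.42 to 7.69 in the other i-KO livers), and the male-biased and female-biased levels of liver WT 8 (4.97 and 5.65) stood apart from the other WT livers (7.48 to 8.23 and 0.289 to 1.71). Female mice among the livers are argued against, since the highest Xist value in liver was 0. Chance between 5 and 5 mice may account for it: an exact permutation test of the mean of the 8 genes over 126 splits gave p = 0.206 (two-sided). No other biological explanation was tested.

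For the changed genes in intestine 1 of 100 splits, the real one, gave as many (4124, next 3037 with WT 7 exchanged for i-KO 2). This argues against chance there. For the difference between tissues it was also 1 of 100 (1829, next 1731). Those splits drew the genotype anew in both tissues at once, so their rank cannot separate a difference between tissues from the intestine effect alone. Chance cannot be excluded for the number of lists called in intestine (15 of 100 splits gave as many as 12, highest other 15). Nor can it for the number called in liver (80 of 100 gave as many as 4, highest other 12). These counts do not measure how strongly a list changed, so they decide nothing about a single list. Some intestine splits also keep most of the labelled groups, such as that with 3037 changed genes. For liver genes the real count was 0, which each of the 100 splits reaches, so the splits decide nothing there. In liver the split with i-KO 6 and WT 8 exchanged called 618 genes. It is the highest of the 99 other splits, and the highest count without any structure of the samples was not computed. The first principal component of liver, with 35.7% of the variance, separated the same sets. On it i-KO 1, 2, 4, 5 and WT 8 lay at -43.9 to 0.507 and the other livers at 10.2 to 23.7. Their male-biased levels were 3.31 to 6.90 against 7.48 to 8.23. The split, the component and these levels come from the same expression values, so their agreement is not independent support. The sets differ from the labelled genotypes only by the exchange of i-KO 6 and WT 8. Whether they mark a structure of the livers beyond chance, and its cause, were not tested.

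Other libraries that stood apart are given as values. Intestine i-KO 1 had a total coverage of 179 kilounits against 941 to 1206. Intestine WT 9 had Xist at 51.2 and Ddx3y at 0, against 15.9 to 19.2 for Ddx3y in the other WT libraries. Liver WT 9, with the same number, had Xist at 0 and Ddx3y at 11.7. The number 9 thus does not stand for a single sex, and the cause was not tested. Intestine i-KO 2 had a PPARA level of 6.18 against 5.23 to 5.39, and i-KO 5 a blood marker level of 3.11 against 1.63 to 1.83. Intestine WT 12 had a Paneth level of 8.67 against 7.18 to 7.50 and a YAP list level of 2.49 against 2.92 to 3.05. Liver WT 7 had Srebf2 at 19.2, Ldlr at 122 and Pcsk9 at 20.1, against at most 12.0, 76.4 and 9.89 in the other WT livers. Liver WT 9 had Cyp7a1 at 88.5 against 19.5 to 32.6. The nonsterol isoprenoid level was 3.05 in liver i-KO 6 (2.79 to 2.85 in the others) and 2.88 in liver WT 12 (2.94 to 2.96), and the Kupffer level was 6.05 in liver i-KO 2 (4.78 to 5.10). The genotype effect differed between tissues for 1829 genes by the interaction test, among them Dio1 (-3.35), Cd36 (-4.24), Pbld1 (-2.38), Lect2 (-3.86), Zfp467 (-2.32), Krba1 (-2.34), Pipox (-2.33), Nrn1 (-1.71), Cse1l (1.31) and Iyd (-3.05), as log2 differences.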

How the results depend on the processing

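Alternatives with other pseudocounts, precision or library weights, small RNA genes left out, or both doubted libraries left out were chosen after seeing the data. The number of changed genes in intestine, 4124, stayed within 1.5 times under each alternative run. It was 2807 to 4950 when single libraries were left out, 4950 without WT 7, 3500 without i-KO 1 and 4408 without both, with 3673 of the 4124 shared. Without both, 17 of 19 cholesterol synthesis genes and 24 of 25 proliferation genes were higher, and 12 of 14 Paneth and 11 of 22 enterocyte markers lower. Hmgcr in intestine passed the test without i-KO 6, and its log2 fold change ran from -0.49 to -0.19 when single libraries were left out. The liver count was 0 under each alternative except the joint fit of all 20 libraries, which called 1 gene, Figf (named after its value was seen); the cause was not tested. Gene lists called in intestine went from 12 to 0 and in liver from 4 to 0 with an estimated correlation. The fry test, which asks whether the genes of a list change at all rather than more than other genes, called 0 in liver and 15 in intestine. There it added nonsterol isoprenoid (adjusted p = 0.0359), circadian (0.0402), goblet (0.00297) and proximal (0.00297) lists and lost the stem cell list (0.0841). When single libraries were left out, the lists called were 10 to 14 in intestine and 2 to 7 in liver, with 7 without liver i-KO 2 and 2 without WT 11. Member counts moved too: without WT 9, 4 stem cell markers were higher and 4 tuft markers lower, and without WT 7 they were 8 and 7.

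The interaction count of 1829 ran from 1158 (without intestine WT 9) to 2500 (without intestine WT 7) when single libraries were left out, and was 2331 without both doubted libraries. The replicate block was possible for the 16 libraries whose title number occurs in both tissues. It called 15 genes, and the same 16 libraries without the block called 156, fewer samples than the 20 of the main result. Libraries with the same number did not deviate together: 1 of 8 pairs had a correlation above 0.1, the range was -0.39 to 0.15, and 1 of 8 libraries correlated best with its own number. This check does not settle whether a shared number is a single mouse, since the tissues of a mouse need not deviate together. For number 9 the Xist values differed, at 51.2 in intestine and 0 in liver. Of 87 named intestine genes past the threshold none changed sign. Of their 1907 values under alternatives 32 lost the threshold, in 8 genes: Rce1, Agr2, Duox2, Duoxa2, Dbp, Nr1d2, Cd8a and Zg16. Of the 10 interaction genes, Cse1l lost it under the block. The tests planned for counts and the sex covariate were not run. Low coverage in intestine i-KO 1 limits what can be read for genes near 1 per 1000000, such as Lgr5.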

Other observations

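These gene lists were written after the leading genes were seen, so all of their tests are chosen after the data. Members that are named intestine genes (Psat1, Cd36, Apob, Cyp2c66 and Cyp3a25) were left out of their lists in the tests in intestine. Other strongly changed members stayed, among them Shmt2 (limma adjusted p = 0.00133). No member was left out of the ribosome biogenesis and tRNA synthetase lists. The list tests are therefore not independent of the data that prompted the lists. In i-KO intestine all 20 tested ribosome biogenesis genes were higher (median log2 fold change 1.22, camera adjusted p = 6.88e-11; adjusted p = 0.358 with an estimated correlation). Ncl, the nucleolar protein nucleolin, rose from 22.6 ± 5.78 to 54.3 ± 11.9. All 16 aminoacyl-tRNA synthetase genes were higher (median 0.74, camera adjusted p = 2.16e-09; adjusted p = 0.358 with an estimated correlation), with Mars going from 20.7 ± 8.84 to 51.7 ± 9.38. Beside Psat1, all 7 tested genes of serine and one-carbon metabolism were higher (median 1.26, camera adjusted p = 6.73e-05; adjusted p = 0.358 with an estimated correlation). Shmt2 rose from 17.2 ± 8.20 to 62.8 ± 9.30 and Mthfd2 from 3.89 ± 1.96 to 15.3 ± 4.53. Proteasome subunits were higher in 13 of 14 cases (median 0.65, camera adjusted p = 4.43e-06; adjusted p = 0.397 with an estimated correlation), and in 9 without i-KO 1 and 8 without WT 9.

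Intestinal cytochrome P450 genes other than Cyp2c66 and Cyp3a25 fell in 4 of 6 cases (median -1.24, camera adjusted p = 0.00513; adjusted p = 0.397 with an estimated correlation), with Cyp2c55 going from 121 ± 34.9 to 20.96 ± 17.7. Lipid absorption genes other than Cd36 and Apob fell in 2 of 9 cases, and the list was not called (camera adjusted p = 0.224). Of 9 NRF2 targets 5 rose and 1 fell (camera adjusted p = 0.0201; adjusted p = 0.397 with an estimated correlation). Gsta1 rose from 46.3 ± 35.2 to 207 ± 97.6, while Gclm fell by 0.77 on the log2 scale. MHC class II (0 of 7 changed), p53 targets (1 up, 1 down of 8), prenylated small GTPases (2 up of 15) and complex I (2 up, 1 down of 10) were not called in intestine (camera adjusted p from 0.161 to 0.958). Without i-KO 1 none of the p53, GTPase and complex I genes passed; without WT 9, 1 p53 target and 1 complex I gene were lower and none higher; without WT 7, 3 p53 targets were lower and 1 higher. In liver 1 of the 11 lists was called, prenylated small GTPases (median -0.22, camera adjusted p = 0.00386; adjusted p = 0.558 with an estimated correlation), with 0 members past the test; the other 10 had camera adjusted p from 0.0707 to 0.862.

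The highest correlation between a pair of liver libraries was that of i-KO 6 and WT 7 (Spearman 0.982, across genes), the same 2 numbers as the pair with the highest correlation between genotypes in intestine (0.982). A fit of intestine WT 7 as a sum of the other 9 libraries gave i-KO 6 a weight of 0.545 and the 4 WT libraries 0.378 together, with a relative residual of 0.0799, the lowest of the 10 libraries fitted in this way. The same fit of i-KO 6 gave its largest weight, 0.696, to WT 7 with a relative residual of 0.233, so the fits show that these libraries are alike and give no direction of mixing.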
